A study of Mus musculus with 16 samples.

How the data were processed

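The data are RNA sequencing of sorted mouse Tregs, in 16 libraries of about 100 cells each, from 4 groups of 4 libraries: injured heart and MLN 7 days after MI, each sorted into CCR8+ and CCR8-. Whether the libraries of a group came from separate mice is not given in the sources used here. Equal replicate numbers were not taken as pairs, and deviations from the group means correlated between them by only -0.0933 to 0.0589.

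The authors prepared libraries with the NEBNext Ultra RNA kit, aligned reads to mm10 (GRCm38) with HISAT2 2.0.5 and counted them with featureCounts 1.5.0-p3. The deposited table holds 19219 genes in 16 columns. Its values were read as log2(FPKM + 1) after quantile normalization by the authors: the highest value was 14.899 in every library, the top 74 ranks were identical, and the values without the log summed to between 1007908 and 1007934. The log and quantile steps are not given in the sources used here. The deposited columns are named FPKM, but sums this close to 1e+06 are also what TPM would give, so FPKM + 1 stands for whichever of these the values are. The plan had assumed FPKM without a log, and the test on log2(FPKM + 1) is the same either way. Read numbers per library are not known, so nothing is said about depth.

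Entries named as dates (24) were left out, which leaves 19195 genes, of which 1966 were at 0 in all libraries. Genes with an FPKM of 1 or more in at least 4 libraries were tested (10369). With R 4.3.3 and limma 3.58.1, 1 linear model with a mean per group was fitted to all 16 libraries (12 residual and 7 prior degrees of freedom, variance trend on). The comparisons were CCR8+ against CCR8- in heart and in MLN, heart against MLN in CCR8+ and in CCR8- Tregs, and the interaction of tissue and CCR8. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 in limma.

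Gene lists were tested with camera in limma, with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over the lists of a comparison. The lists were written from general knowledge and no gene is in more than 1. There are 14 function lists (Treg identity, effector Treg and checkpoint, tissue repair Treg, resting lymphoid T cell, tissue homing receptor, cytokine and chemokine, T cell receptor response, NF-kB pathway, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, lipid and cholesterol, interferon response, immediate early and dissociation stress). The 10 cell type lists are general T cell, cardiomyocyte, fibroblast, macrophage and monocyte, neutrophil, B cell, dendritic cell, cytotoxic T and NK cell, endothelial cell and erythroid cell. Of their 430 genes 422 were present, and 23 lists with at least 5 measured genes were tested. Overlap between comparisons was tested with a one-sided Fisher's exact test.

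Named genes are those chosen in advance (Ccr8, Foxp3, Il2ra, Ctla4, Areg, Il1rl1, Gata3, Batf, Klrg1, Il10, Tnfrsf9, Ccr7 and Tcf7), the 8 called genes with the largest difference per direction and comparison whose 4 libraries all lie above the 4 of the other group (5 per direction for the interaction, without that condition), and up to 4 called genes per list, of which the text gives examples. In all, 118 of these genes were followed under every setting, and a few that the rule selects are not reported here. Unnamed transcripts, pseudogenes and receptor segments were passed over. Coordinates are from GENCODE vM21, which had 1 entry for 117 of these 118. The groups, comparisons, tests, lists, naming rule and other settings to try were set before the data were examined.

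The other settings planned were a pseudocount of 0.1, no filter, an FPKM of 5 in at least 4 libraries, median-of-ratios factors, rescaling each library to the same sum, quantile normalization, only the 2 groups compared, a replicate block, array weights, an estimated correlation, fry, and leaving out each library in turn. A covariate for other cell types (the mean of the fibroblast, macrophage and endothelial list means) and the removal of 2 heart libraries were added after seeing the data, as was a permutation of residuals for the interaction. The procedure was tested on simulated data: of changes of 1, 2 and 3 on the log2 scale it recovered 8.96, 35.4 and 60.3% in heart CCR8+ against CCR8-, 9.84, 40.3 and 59.7% in MLN CCR8+ against CCR8-, 3.39, 22.9 and 40.8% in heart CCR8+ against MLN CCR8+, 7.58, 31.6 and 61.0% in heart CCR8- against MLN CCR8-, and 2.86, 9.23 and 23.1% in the interaction. There were 13 false calls among 87 in MLN CCR8+ against CCR8-, 0 in the others, and no wrong signs. Each comparison was simulated once, with residuals shuffled over all 16 libraries, so the 4 comparisons of groups were simulated alike. Differences between these 4 in recovery and false calls therefore reflect single draws. Fewer genes were changed than were called in the largest real comparisons.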

Results

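RNA was sequenced from regulatory T cells (Tregs), the Foxp3-expressing T cells that restrain immune responses, of 8-week-old Foxp3-GFP reporter mice 7 days after myocardial infarction (MI). The cells came from the injured heart and from the mediastinal lymph node (MLN), which drains the chest, and were sorted by surface CCR8, a chemokine receptor known from Tregs that reside in tissues. This gave 4 groups (heart CCR8-, heart CCR8+, MLN CCR8- and MLN CCR8+) of 4 libraries each, made from about 100 cells per library. Expression is given as log2(FPKM + 1), as mean ± SD over the 4 libraries of a group, and differences are on the log2 scale. The unit follows the name FPKM in the data, and whether the values are FPKM or TPM was not settled. A fold is the ratio of the values + 1. Where a gene is listed at 0, the size of its difference, and of a list median that includes it, depends on the added 1. The number of reads per library is unknown, so no counting error can be given. Genes above 0 numbered 11142 to 12704 in the heart CCR8- libraries, 10789 to 11867 in heart CCR8+, 10691 to 10906 in MLN CCR8- and 11041 to 11565 in MLN CCR8+. In a principal component analysis the first component held 22.6% of the variance, and all 8 heart libraries (-74.11 to -19.05) lay apart from all 8 MLN libraries (10.38 to 73.99). The p values of single genes measure the spread between libraries, and it is not stated whether these came from separate mice. Those of camera set the genes of a list against the other genes. Fisher's exact test counts genes as if independent, which they are not. The comparisons it joins also share 1 estimate of the spread per gene, so the numbers expected can be too low. No overlap, where given below, means that all 4 libraries of 1 group lie above all 4 of the other, and the genes given with the largest differences were chosen for it. Other called genes did overlap, among them Areg in MLN CCR8+ against CCR8-, and Ctla4 and Ifit3 in heart CCR8- against MLN CCR8-.

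Ccr8 mRNA followed the sort in each tissue and was higher in heart than in MLN. The gene (chromosome 9, 120092114 to 120094906 in GRCm38) averaged 10.01 ± 0.30 in heart CCR8+, 8.45 ± 0.24 in heart CCR8-, 7.78 ± 0.40 in MLN CCR8+ and 4.60 ± 0.66 in MLN CCR8- Tregs. Every heart CCR8- library (8.20 to 8.73) was above every MLN CCR8+ library (7.39 to 8.18). Foxp3, the lineage factor of Tregs, averaged 5.36 ± 0.42, 4.90 ± 0.59, 5.10 ± 0.41 and 5.58 ± 0.80 in heart CCR8-, heart CCR8+, MLN CCR8- and MLN CCR8+ Tregs, and none of its comparisons passed the test (adjusted p from 0.329 to 0.796). Batf, a transcription factor of effector Tregs, averaged between 8.45 and 8.68 in the 4 groups, and none of its comparisons passed either (adjusted p from 0.757 to 0.984).

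**Figure D1:**
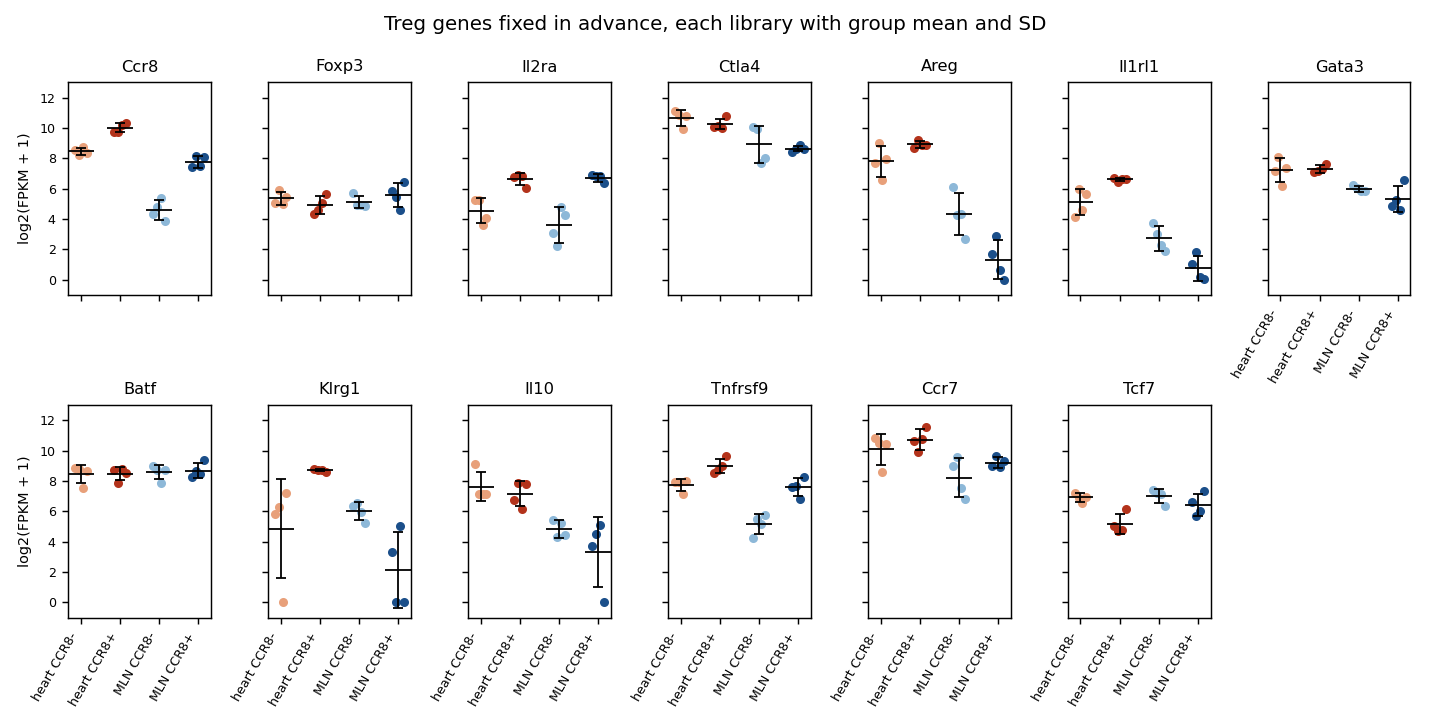
The 13 Treg genes shown, chosen in advance, as log2(FPKM + 1) in each library (points) with the mean and SD of each group of 4 libraries (black). The 4 heart CCR8+ libraries lie between 9.75 and 10.32 for Ccr8 and between 8.69 and 9.20 for Areg.

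Transcripts of other cell types were measured in the sorted Tregs, more in the heart libraries than in those of the MLN. The mean of 12 general T cell genes was similar in level across groups: 8.05 ± 0.49 in heart CCR8-, 7.73 ± 0.30 in heart CCR8+, 7.97 ± 0.13 in MLN CCR8- and 8.12 ± 0.29 in MLN CCR8+. Fibroblast markers averaged 2.84 ± 0.83 in heart CCR8- and 1.97 ± 1.09 in heart CCR8+, against 0.21 ± 0.15 in MLN CCR8- and 0.07 ± 0.08 in MLN CCR8+. Macrophage and monocyte markers averaged 3.89 ± 0.72 and 3.89 ± 2.29 in heart CCR8- and CCR8+, against 0.93 ± 0.17 and 1.63 ± 0.41 in MLN CCR8- and CCR8+. Endothelial markers averaged 2.43 ± 2.12 and 1.12 ± 0.40 in the same heart groups, with 5.55 in heart CCR8- replicate 3. Heart CCR8+ replicate 1 held the least of these in its group, with 0.41 for fibroblast and 0.99 for macrophage markers. Among MLN groups, B cell markers averaged 2.27 ± 0.89 in CCR8+ and 0.98 ± 0.60 in CCR8- libraries, and dendritic cell markers 2.17 ± 0.34 and 1.12 ± 0.77.

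**Figure D2:**
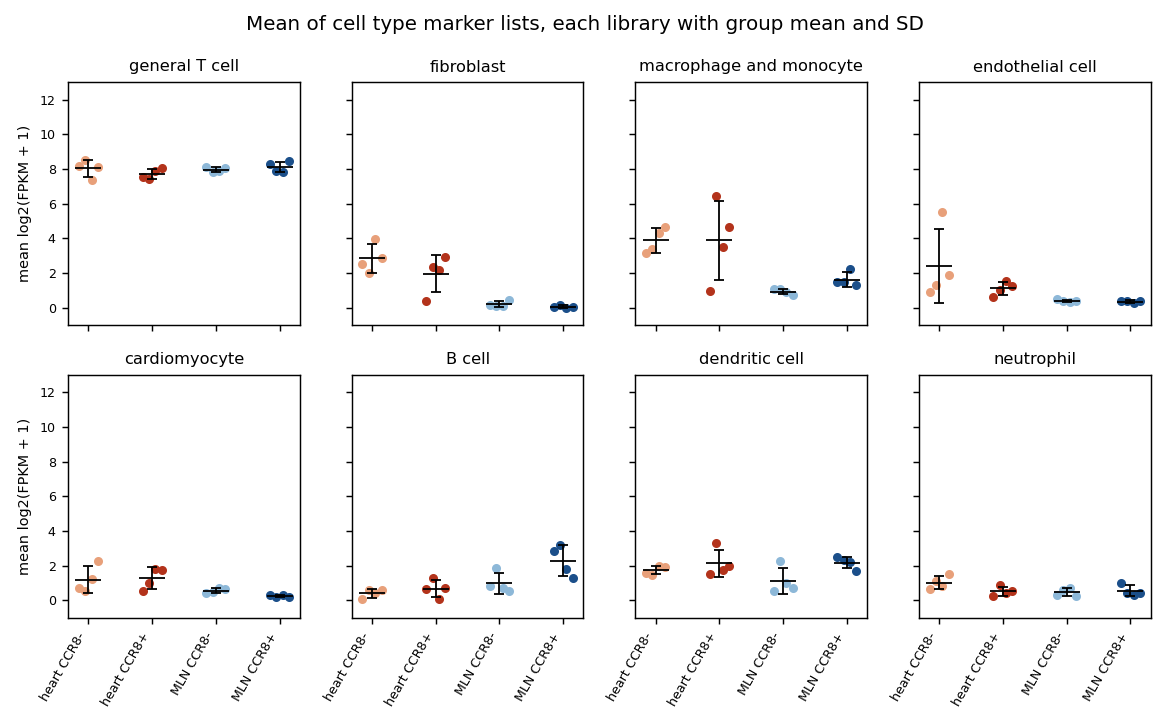
Mean log2(FPKM + 1) of the marker genes of 8 cell types in each library (points), with the mean and SD of each group of 4 libraries (black). Fibroblast and macrophage markers are higher in most heart libraries than in the MLN libraries, while general T cell genes stay between 7.36 and 8.53.

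Among Tregs of the injured heart, few genes passed the test between CCR8+ and CCR8- cells. Many differences can be missed here: of simulated changes of 1, 2 and 3 on the log2 scale, 8.96, 35.4 and 60.3% were recovered. The question is what sets CCR8+ Tregs apart within the tissue. Pdzk1ip1, a small membrane protein, averaged 5.75 ± 1.01 in CCR8+ and 0.05 ± 0.09 in CCR8- cells, a difference of 5.70 ± 0.74 (SE, adjusted p = 0.00156). Tff1, a secreted trefoil peptide of epithelia, averaged 5.80 ± 1.71 in CCR8+ and 0.37 ± 0.75 in CCR8- cells (adjusted p = 0.00141), and it was listed at 0 in all 8 MLN libraries. Calca, which encodes calcitonin and the neuropeptide CGRP, averaged 8.65 ± 0.55 against 4.52 ± 2.35 (adjusted p = 0.0285). Csf2, the growth factor GM-CSF, averaged 2.88 ± 0.33 in CCR8+ cells and was listed at 0 in all 4 CCR8- libraries (adjusted p = 0.0209). Pdzk1ip1 lies on chromosome 4 (115088708 to 115093899), Tff1 on chromosome 17 (31161395 to 31165277) and Calca on chromosome 7 (114631478 to 114636357).

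In all, 28 genes were higher and 10 lower in heart CCR8+ than in heart CCR8- Tregs among 10369 tested, and 30 of the 38 differed by 2-fold or more. Ccr8 itself was 2.94-fold higher (adjusted p = 0.0234). The 8 higher genes with the largest differences and no overlap between the groups were Pdzk1ip1, Tff1, Calca, Ak6, Mlf1, Rabepk, Csf2 and Comtd1. The 8 lower genes were Rad9a, Dpt, Rasgrp2, Tcf7, Ppcdc, Kcnh6, Tpt1 and Atp5md. Rad9a, a part of the DNA damage checkpoint clamp, fell by 3.14 (adjusted p = 0.0209). Rasgrp2, an activator of the GTPase Rap1, fell by 2.33 (adjusted p = 0.0329), and Tcf7, a transcription factor of naive and memory T cells, fell by 1.74 (adjusted p = 0.0472). Il1r2, the decoy receptor for interleukin 1, rose by 2.15 (adjusted p = 0.0437). Il1r2 and Ccr8 also showed no overlap between the groups. Il2ra, the interleukin 2 receptor alpha chain, averaged 6.63 ± 0.41 against 4.52 ± 0.83 (adjusted p = 0.0755), and Areg and Klrg1 did not pass (adjusted p = 0.552 and 0.209).

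Of the 18 measured genes of resting lymphoid T cells, 1 fell, none rose and 17 did not pass, while adjusted over the list alone 2 fell. Their median difference was -0.86, and the list passed with a preset correlation between genes (adjusted p = 6.48e-05) but not with an estimated one (adjusted p = 0.276 with an estimated correlation). Of 20 immediate early and dissociation stress genes none passed alone and 2 fell adjusted over the list alone, with a median of -0.85 (adjusted p = 2.21e-05, and adjusted p = 0.276 with an estimated correlation). The cell cycle, glycolysis and hypoxia, and oxidative phosphorylation lists were higher with medians of 0.48, 0.38 and 0.18, each with an adjusted p of 0.0213. None of these held with an estimated correlation (adjusted p = 0.427, 0.354 and 0.276 in that order), and no member passed over all genes; adjusted over the list alone, 1, 1 and 0 members rose. Fibroblast and endothelial markers were lower in the CCR8+ libraries, with medians of -0.99 and -1.35 (adjusted p = 0.00667 and 0.00895, and adjusted p = 0.453 and 0.387 with an estimated correlation). The count of 38 genes became 13 with no filter on low values, 5 with only the 2 groups compared and 20 with a replicate block. With 2 settings chosen after seeing the data it was 17 (markers of other cells as a covariate) and 11 (2 heart libraries left out). It became 3 without heart CCR8+ replicate 3, 4 without heart CCR8+ replicate 1, 8 without heart CCR8+ replicate 2 and 11 without heart CCR8- replicate 2. Of the 19 called genes among 118 followed under every setting, Pdzk1ip1 and Tff1 kept their calls whichever library was left out, and the other 17 lost theirs in at least 1 such fit. Only Pdzk1ip1 kept its call in every setting tried.

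In the MLN, the Treg identity and T cell receptor response lists were higher in CCR8+ than in CCR8- Tregs. Il2ra rose 8.74-fold, to 6.71 ± 0.26 from 3.59 ± 1.18 (adjusted p = 0.00131), and Izumo1r, the folate receptor 4 of Tregs, rose 5.08-fold to 10.81 ± 0.23 (adjusted p = 1.24e-04). Myc, a transcription factor of growth and biosynthesis, rose 18.9-fold to 7.58 ± 0.50 (adjusted p = 4.57e-04), and Ccr8 rose 9.07-fold (adjusted p = 3.00e-06). S100a4 and S100a6, neighbouring genes of calcium-binding proteins abundant in effector and memory T cells, fell by 6.53 and 4.53 (adjusted p = 8.26e-05 and 5.38e-06). S100a4 averaged 6.04 ± 2.56 in MLN CCR8+ Tregs and between 12.14 and 12.57 in the other groups. Ccr2, a chemokine receptor for entry into inflamed tissue, fell by 4.57 to 1.12 ± 1.25 (adjusted p = 3.34e-04).

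These genes lie at 11642807 to 11693193 on chromosome 2 (Il2ra), 14885814 to 14903949 on chromosome 9 (Izumo1r), 61985391 to 61990374 on chromosome 15 (Myc), 90603771 to 90606045 on chromosome 3 (S100a4), 90612882 to 90624181 on chromosome 3 (S100a6) and 124101950 to 124113557 on chromosome 9 (Ccr2). In all, 212 genes were higher and 217 lower in MLN CCR8+ than in MLN CCR8- Tregs, and 345 of the 429 differed by 2-fold or more. This even split depended on the scaling: median-of-ratios factors gave 273 higher and 174 lower. Higher genes with the largest differences and no overlap were Srm, Myc, Apoe, Capn3, Smyd2, Slc22a2 and Galk1, with differences of 3.74 to 4.28. Srm makes the polyamine spermidine, and Apoe is the lipid carrier of macrophages and other cells. The 8 lower genes were S100a4, Ramp3, Lgmn, Gzmb, Ccr2, S100a6, Rnf125 and Gna15. Ramp3, a partner of calcitonin-family receptors, fell by 5.07 (adjusted p = 0.00342), and Lgmn, a lysosomal protease, fell by 4.89 (adjusted p = 1.79e-04). Gzmb, the protease granzyme B, averaged 4.61 ± 2.26 in CCR8- cells and was listed at 0 in all 4 CCR8+ libraries (adjusted p = 0.00502).

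Of the 14 Treg identity genes, 7 rose, none fell and 7 did not pass, and adjusted over the list alone 9 rose. Their median was 1.42, and the list passed with either correlation (adjusted p = 8.46e-10, and adjusted p = 0.0488 with an estimated correlation). Of 18 T cell receptor response genes 4 rose, 1 fell and 13 did not pass (5 and 1 adjusted over the list alone), with a median of 0.85 (adjusted p = 2.78e-04, and adjusted p = 0.0488 with an estimated correlation). Besides Myc, these held Rgs16, a regulator of G protein signalling (3.52, adjusted p = 0.00794), and Irf8, a transcription factor shared with dendritic cells and B cells (3.01, adjusted p = 0.00839). Of 22 glycolysis and hypoxia genes 3 rose and 19 did not pass (6 rose adjusted over the list alone), with a median of 0.65 (adjusted p = 0.00134, and adjusted p = 0.155 with an estimated correlation). Gapdh, one of these 3, rose by 0.99 (adjusted p = 0.00268). Of 19 tissue repair Treg genes 4 fell and 15 did not pass (6 fell adjusted over the list alone), with a median of -0.56 (adjusted p = 0.0201, and adjusted p = 0.0637 with an estimated correlation). Among them, Areg, the growth factor amphiregulin, fell by 3.03 (adjusted p = 0.0103), and Rora, a nuclear receptor, fell by 3.27 (adjusted p = 0.00173). Of 17 homing receptor genes 6 fell, 2 rose and 9 did not pass (7 and 2 adjusted over the list alone), with a median of -1.46 (adjusted p = 0.0201, and adjusted p = 0.386 with an estimated correlation).

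Some genes of effector Tregs rose and others fell in MLN CCR8+ cells. Of the 21 measured effector and checkpoint genes 4 rose, 5 fell and 12 did not pass (10 and 6 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.608). Tnfrsf9, a costimulatory receptor, rose by 2.42 (adjusted p = 6.46e-04) and Cd83 by 2.09 (adjusted p = 0.00343), while Tigit, an inhibitory receptor, fell by 1.75 (adjusted p = 9.53e-04) and Glrx, a glutaredoxin, by 1.99 (adjusted p = 0.00185). Of 18 resting lymphoid genes 1 rose and 2 fell (1 and 4 adjusted over the list alone; adjusted p = 0.207 for the list). Bcl2, which blocks apoptosis, rose by 2.07 (adjusted p = 0.0103), and S1pr1, which directs exit from lymph nodes, fell by 2.56 (adjusted p = 0.00357). Of 6 dendritic cell markers 1 rose, none fell and 5 did not pass (4 rose adjusted over the list alone), with a median of 2.87 (adjusted p = 0.0395, and adjusted p = 0.288 with an estimated correlation, 0.0656 with median-of-ratios factors). The gene that rose, H2-Ab1 (adjusted p = 0.0498), lost its call in 14 of the 16 fits with 1 library left out, and its groups overlapped. None of the 4 measured B cell markers passed (2 rose adjusted over the list alone). Their median was 2.33, and Cd79a, of the B cell receptor, averaged 6.40 ± 1.42 against 3.30 ± 2.15 (adjusted p = 0.0658). The count of 429 genes became 169 with only the 2 groups compared, 273 without MLN CCR8+ replicate 4 and 283 without MLN CCR8+ replicate 1. Some of the falls rest in part on MLN CCR8- replicates 1 and 2: Rora was 5.90 and 5.85 there against 2.78 and 4.16 in replicates 3 and 4, Rnf125 8.25 and 7.88 against 4.68 and 4.86, and S1pr1 9.26 and 8.88 against 7.15 and 6.62. Whether a batch separates these replicates was not tested. Of 52 called genes among those 118, 34 kept their calls whichever library was left out, and Galk1, Smyd2 and Slc22a2 were among the 18 that did not.

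Few genes were called for CCR8 in both heart and MLN, a count limited by the 38 called in heart. Of the 212 genes called higher in MLN CCR8+ cells, 71.7% were also higher in heart CCR8+ cells, called or not. Of the 217 called lower, 66.8% were also lower in heart CCR8+ cells. The median heart difference of all genes was 9.04e-05. Called higher in both were Bmyc, C1qbp, Ccr8, Mif, Nme1, Pdzk1ip1, Psmb8 and Rpl32, 8 genes against 0.572 expected if the calls were independent (one-sided Fisher's exact test, p = 5.85e-08). Called lower in both were Kcnh6, a potassium channel subunit, and Rasgrp2, against 0.209 expected (p = 0.0176 by the same exact test). In each direction, 1 gene called in the heart was called the opposite way in the MLN. Across all genes, which are not independent replicates, Pearson's r between the heart and MLN differences was 0.112. These genes were chosen by their calls after the values were seen. The count of 10 shared genes was 3 with no filter on low values and 6 with a replicate block, and with the settings chosen after seeing the data 5 (covariate) and 2 (2 heart libraries left out). It was lower without 7 of the 16 libraries: 1 without heart CCR8+ replicate 3, 2 without heart CCR8+ replicate 1, 3 without heart CCR8+ replicate 2, 4 without heart CCR8- replicate 2 or MLN CCR8+ replicate 2, 5 without MLN CCR8+ replicate 1 and 6 without MLN CCR8- replicate 1.

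**Figure D3:**
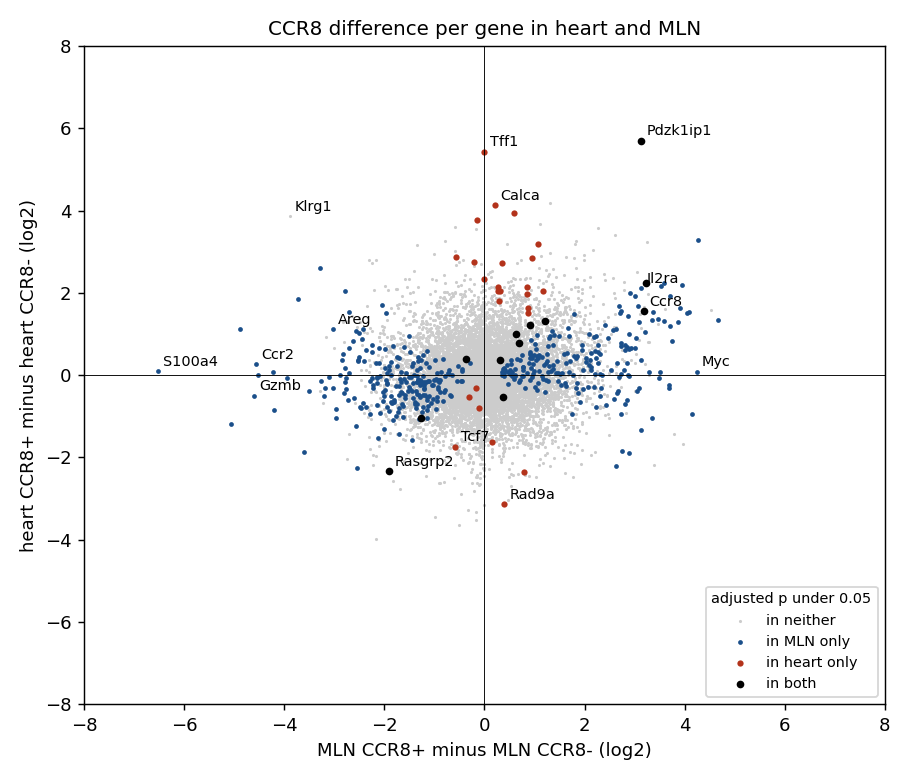
Difference between CCR8+ and CCR8- Tregs on the log2 scale for each of the 10369 genes, in MLN (horizontal) and heart (vertical), coloured by the comparison in which the gene passed. S100a4, Ccr2 and Gzmb lie far to the left near the horizontal zero line, and Ccr8 and Pdzk1ip1 are among the 10 genes that passed the same way in both.

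Among CCR8+ Tregs, heart cells had far more of the genes of tissue repair, effector function and cytokines than MLN cells. The comparison asks how CCR8+ Tregs differ between the injured organ and its node. Areg was 194-fold higher, at 8.91 ± 0.21 against 1.31 ± 1.27 (adjusted p = 7.08e-07), and Il1rl1, the interleukin 33 receptor ST2, was 57.9-fold higher, at 6.60 ± 0.13 against 0.74 ± 0.82 (adjusted p = 9.76e-07). Calca was 327-fold higher, at 8.65 ± 0.55 against 0.29 ± 0.58 (adjusted p = 1.39e-06), and Klrg1, a receptor of terminally differentiated Tregs, was 97.0-fold higher, at 8.71 ± 0.07 against 2.11 ± 2.51 (adjusted p = 0.0013). Gzmb averaged 7.42 ± 1.26 in heart CCR8+ cells and was listed at 0 in all 4 MLN CCR8+ libraries (adjusted p = 2.05e-05). The genes lie at 91139599 to 91148432 on chromosome 5 (Areg), 40429570 to 40465415 on chromosome 1 (Il1rl1), 122270596 to 122282882 on chromosome 6 (Klrg1) and 56258838 to 56262260 on chromosome 14 (Gzmb).

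In all, 603 genes were higher and 412 lower in heart CCR8+ than in MLN CCR8+ Tregs, and 892 of the 1015 differed by 2-fold or more. The count of lower genes became 239 without MLN CCR8+ replicate 4, 261 without heart CCR8+ replicate 2 and 265 without MLN CCR8+ replicate 1, and that of higher genes 457, 451 and 473. Of 80 called genes among the 118 followed, 61 kept their calls whichever library was left out. The 8 higher genes with the largest differences and no overlap were Calca, Ramp3, Areg, Cxcl1, Gzmb, Cdkn1a, Klrg1 and Cxcl2. Cxcl1 and Cxcl2 encode neutrophil-attracting chemokines, and Cdkn1a the cell cycle inhibitor p21. Ramp3 was higher by 7.66 (adjusted p = 2.34e-05) and Cxcl2 by 6.58 (adjusted p = 1.09e-05), while Cxcl1, at 7.46 ± 2.01, and Cdkn1a, at 6.68 ± 0.68, were listed at 0 in all 4 MLN CCR8+ libraries. The 8 lower genes were Apol9b, Cd79a, Cxcr5, Nudt22, Apobec2, Fdxr, Actg2 and Slc22a5. Apol9b, an interferon-inducible apolipoprotein, fell by 5.66 (adjusted p = 7.74e-07), and Cxcr5, the receptor for entry into B cell follicles, fell by 4.18 (adjusted p = 1.18e-04). Cd79a fell by 5.17 (adjusted p = 0.00121).

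Of the 19 tissue repair Treg genes 12 rose, none fell and 7 did not pass (15 rose adjusted over the list alone), with a median of 2.95 (adjusted p = 1.20e-14, and adjusted p = 3.15e-05 with an estimated correlation). Besides Areg and Il1rl1, Dgat1, an enzyme of triglyceride synthesis, rose by 5.68 (adjusted p = 2.05e-04), Rora by 4.93 (adjusted p = 7.73e-06) and Gata3, a transcription factor of tissue Tregs, by 1.97 (adjusted p = 0.00294). Of 21 effector and checkpoint genes 9 rose and 12 did not pass (10 rose adjusted over the list alone), with a median of 1.11 (adjusted p = 1.91e-06, and adjusted p = 0.0204 with an estimated correlation). Tigit rose by 2.69 (adjusted p = 2.14e-06), and Il10, an inhibitory cytokine, by 3.83 (adjusted p = 0.00365), while Havcr2, the receptor TIM-3, averaged 4.49 ± 0.72 and was listed at 0 in all 4 MLN CCR8+ libraries. Of 15 cytokine and chemokine genes 8 rose and 7 did not pass (10 rose adjusted over the list alone), with a median of 2.87 (adjusted p = 3.55e-06, and adjusted p = 0.0204 with an estimated correlation). Spp1, the matrix cytokine osteopontin, was among them at 4.84 ± 2.97, with 0.42 in heart CCR8+ replicate 1. Of 17 homing receptor genes 6 rose, 2 fell and 9 did not pass (7 and 2 adjusted over the list alone), with a median of 0.83 (adjusted p = 0.00868, and adjusted p = 0.341 with an estimated correlation). Cxcr6 rose by 6.53 (adjusted p = 0.00658) and Ccr2 by 5.48 (adjusted p = 1.34e-05), while Ccr3, at 5.76 ± 0.63, was listed at 0 in all 4 MLN CCR8+ libraries.

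Of 20 NF-kB pathway genes 5 rose, 1 fell and 14 did not pass (8 and 1 adjusted over the list alone), with a median of 0.58 (adjusted p = 0.00465, and adjusted p = 0.399 with an estimated correlation). Rel, an NF-kB subunit, rose by 2.55 (adjusted p = 2.36e-04), and Tnfaip3, its feedback inhibitor A20, by 3.60 (adjusted p = 7.09e-04). Of 20 immediate early and dissociation stress genes 4 rose, 1 fell and 15 did not pass (5 and 1 adjusted over the list alone; median 0.51, adjusted p = 0.0348, and adjusted p = 0.535 with an estimated correlation). Of 14 Treg identity genes 2 rose and 3 fell (2 and 6 adjusted over the list alone; adjusted p = 0.0647 for the list), with Ctla4, an inhibitory receptor, higher by 1.63 (adjusted p = 0.0141) and Izumo1r lower by 2.44 (adjusted p = 2.34e-05). Of 18 resting lymphoid genes 6 fell, 2 rose and 10 did not pass (6 and 4 adjusted over the list alone; adjusted p = 0.406 for the list), among them Bcl2, which fell by 2.26 (adjusted p = 0.00247). Markers of other cells rose in the same comparison. Of 11 fibroblast markers 7 rose (median 2.24, adjusted p = 7.40e-07), of 15 macrophage and monocyte markers 5 rose (median 2.50, adjusted p = 7.06e-06) and of 9 cardiomyocyte markers 2 rose (median 2.22, adjusted p = 0.00868). With an estimated correlation these lists did not pass (adjusted p = 0.302, 0.399 and 0.302 in that order), and adjusted over the list alone 8, 8 and 5 of their members rose. With the level of fibroblast, macrophage and endothelial markers as a covariate, a setting chosen after seeing the data, 406 genes passed in place of 1015: the median size of the 1015 differences went from 2.06 to 1.90 and their median standard error from 0.48 to 0.61. Areg (8.03), Calca (9.62), Klrg1 (8.44) and Gzmb (7.29) still passed, while Sparc went from 4.81 to 1.68 and Spp1 from 4.84 to 2.23 (adjusted p = 0.274 and 0.157). Cxcl1 also passed but went from 7.465 to 5.20. Among heart CCR8+ libraries, Cxcl1 and the marker level were both lowest in replicate 1 (4.70 and 0.68) and highest in replicate 2 (9.45 and 3.28).

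Among CCR8- Tregs, heart cells again had more tissue repair, effector and cytokine genes than MLN cells, along with many genes of activation and of other heart cells. The comparison asks how Tregs without surface CCR8 differ between the organ and its node. Areg was 10.9-fold higher, at 7.79 ± 1.002 against 4.34 ± 1.39 (adjusted p = 0.00364), and Ccr8 mRNA was 14.5-fold higher (adjusted p = 1.70e-07). Cxcl1 was 250-fold higher, at 8.13 ± 1.27 against 0.16 ± 0.19 (adjusted p = 6.37e-06), and Cxcl2 168-fold higher (adjusted p = 1.06e-05). Mgp, a matrix protein of fibroblasts and vessels, was 496-fold higher, at 9.47 ± 1.76 against 0.51 ± 0.69 (adjusted p = 1.90e-04). Cxcl1 lies on chromosome 5 (90891241 to 90893115) and Mgp on chromosome 6 (136872435 to 136875823).

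In all, 306 genes were higher and 167 lower in heart CCR8- than in MLN CCR8- Tregs, and 418 of the 473 differed by 2-fold or more. The share of higher genes, 64.7%, was 74.7% with median-of-ratios factors (355 higher and 120 lower). The 8 higher genes with the largest differences and no overlap were Mgp, Fabp4, Cxcl1, Sparc, Cxcl2, Spp1, C1qb and Lyz2, most of which are known from fibroblasts, endothelium or macrophages. The 8 lower genes were Ifi214, Ifit1bl1, Nprl2, Nudt22, Orc5, Selenoo, Dhrs7b and Ccdc69. Ifi214, of an interferon-inducible family, fell by 4.78 (adjusted p = 2.80e-04).

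Of 20 immediate early and dissociation stress genes 9 rose and 11 did not pass (17 rose adjusted over the list alone), with a median of 1.62 (adjusted p = 2.99e-16, and adjusted p = 0.00713 with an estimated correlation). Atf3, a stress transcription factor, rose by 4.95 (adjusted p = 9.89e-04) and Fosb, an AP-1 subunit, by 3.69 (adjusted p = 0.00199). Of 20 NF-kB pathway genes 6 rose and 14 did not pass (8 rose adjusted over the list alone; median 1.27, adjusted p = 1.50e-09, and adjusted p = 0.0357 with an estimated correlation). Rel rose by 3.12 (adjusted p = 9.18e-05), and Nfkbia, the inhibitor IkB alpha, by 1.92 (adjusted p = 2.13e-05). Of 18 T cell receptor response genes 4 rose and 14 did not pass (6 rose adjusted over the list alone; median 1.32, adjusted p = 5.47e-06, and adjusted p = 0.0103 with an estimated correlation), with Bhlhe40 higher by 3.89 (adjusted p = 4.53e-04) and Nr4a3 by 4.04 (adjusted p = 0.00109). Of 21 effector and checkpoint genes 6 rose and 15 did not pass (9 rose adjusted over the list alone; median 1.15, adjusted p = 2.05e-08, and adjusted p = 0.00713 with an estimated correlation), with Tnfrsf9 higher by 2.57 (adjusted p = 2.80e-04) and Tnfrsf1b, a receptor for tumour necrosis factor, by 2.33 (adjusted p = 0.00157). Of 19 tissue repair genes 5 rose and 14 did not pass (10 rose adjusted over the list alone; median 1.80, adjusted p = 9.11e-10, and adjusted p = 3.51e-04 with an estimated correlation). Dgat1 rose by 4.21 (adjusted p = 0.0057), Dgat2 by 3.59 (adjusted p = 0.00495) and Il1rl1 by 2.38 (adjusted p = 0.0137). Of 15 cytokine and chemokine genes 5 rose and 10 did not pass (5 adjusted over the list alone; median 1.68, adjusted p = 3.82e-05, and adjusted p = 0.0295 with an estimated correlation).

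Calls of 4 other function lists in this comparison were lost with an estimated correlation. Of 14 Treg identity genes 2 rose (4 adjusted over the list alone; median 0.74, adjusted p = 1.96e-04, and adjusted p = 0.102 with an estimated correlation), Ctla4 by 1.75 (adjusted p = 0.0171) and Tnfrsf18, the receptor GITR, by 1.06 (adjusted p = 0.00141). Of 22 glycolysis and hypoxia genes 1 rose (3 adjusted over the list alone; median 0.39, adjusted p = 0.00994, and adjusted p = 0.15 with an estimated correlation). That gene was Hilpda, a lipid droplet protein induced by hypoxia (2.25, adjusted p = 1.48e-04). Of 21 interferon response genes 3 fell and none rose (5 fell and 1 rose adjusted over the list alone; median -0.72, adjusted p = 4.01e-04, and adjusted p = 0.163 with an estimated correlation), among them Ifit3, by 3.01 (adjusted p = 0.0273). Of 21 oxidative phosphorylation genes 1 fell (1 adjusted over the list alone; median -0.23, adjusted p = 0.0435, and adjusted p = 0.102 with an estimated correlation; adjusted p = 0.246 with median-of-ratios factors).

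Markers of other cells rose with these lists. Of 11 fibroblast markers 7 rose (median 3.19, adjusted p = 9.86e-13), of 15 macrophage and monocyte markers 8 rose (median 3.96, adjusted p = 7.30e-11) and of 5 endothelial markers 1 rose, Fabp4 (median 2.41, adjusted p = 3.90e-05). With an estimated correlation none of the 3 lists passed (adjusted p = 0.053, 0.102 and 0.102 in that order), and adjusted over the list alone 9, 11 and 4 of their members rose. With the level of these markers as a covariate, chosen after seeing the data, 16 genes passed in place of 473: the median size of the 473 differences went from 2.20 to 1.78 while their median standard error went from 0.50 to 0.78. Calca, Ccr8, Cxcl1, Cxcl2, Hilpda and Tnfrsf18 were among the 8 of 59 called genes, out of the 118 followed, that passed in every setting tried. The tissue repair genes Areg, Dgat1, Dgat2 and Il1rl1 were not among these 8. The count of 473 became 305 with no filter on low values, 204 with only the 2 groups compared, 266 without MLN CCR8- replicate 4 and 286 without MLN CCR8- replicate 3. Of the 59 called genes, 40 kept their calls whichever library was left out, and Ctla4, Ifit3, Il1rl1 and Nudt22 were among the 19 that did not.

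The tissue difference was shared widely between CCR8+ and CCR8- Tregs. Called higher in heart in both were 202 genes, among them Areg, Calca, Cxcl1, Cxcl2, Dgat1, Bhlhe40 and Hilpda, against 17.8 expected (one-sided Fisher's exact test, p = 5.64e-184). The 202 also held genes known from other cells, among them Mgp, Fabp4, Sparc and Cd14. Called lower in both were 37 genes, among them Nudt22, Ifit1bl1 and Psmb8, against 6.64 expected (p = 4.58e-18 by the same exact test). Another 3 genes in each direction were called the opposite way, and Pearson's r across all genes was 0.453. The shared count of 239 became 156 with no filter on low values, 152 without MLN CCR8- replicate 4, 154 without MLN CCR8- replicate 3, and 14 with markers of other cells as a covariate.

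The CCR8 difference itself depended on tissue for 42 genes, 30 with a more positive CCR8+ minus CCR8- difference in heart and 12 with a more negative one. With no filter on low values the count was 18 (14 and 4). With 1 library left out it lay between 28 and 62, with 38 and 24 without MLN CCR8+ replicate 3, and 41 and 19 without MLN CCR8- replicate 3. Most of the interaction genes named here had their large CCR8 difference in the MLN. S100a6 differed by -0.01 in heart and -4.53 in MLN (interaction 4.53, adjusted p = 8.68e-04), and S100a4 by 0.10 and -6.53 (interaction 6.62, adjusted p = 0.00671). Lgmn differed by 1.13 and -4.89 (interaction 6.02, adjusted p = 0.00216) and Ccr2 by 0.27 and -4.57 (interaction 4.83, adjusted p = 0.0119). In the other direction, Izumo1r differed by -0.01 in heart and 2.34 in MLN (interaction -2.35, adjusted p = 0.00975), and Apol9b by -1.86 and 2.75 (interaction -4.61, adjusted p = 0.00263). The 5 largest positive interactions were Klrg1, S100a4, Lgmn, Ccr3 and Klhl28, and the 5 largest negative ones Haus5, Egr1, Apol9b, Snapc2 and Myc.

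The tissue repair list had a more positive CCR8 difference in heart than in MLN, where its median was -0.56. In heart CCR8+ against CCR8- this list did not pass in camera (median 0.09, adjusted p = 0.15, and adjusted p = 0.354 with an estimated correlation). Of its 19 measured genes 1 passed, Il1rl1 (interaction 3.48, adjusted p = 0.0452), and 3 did adjusted over the list alone, with a median of 1.001 (adjusted p = 0.00149, and adjusted p = 0.0371 with an estimated correlation). Of 14 Treg identity genes 1 had a more negative difference, Izumo1r (5 adjusted over the list alone; median -1.28, adjusted p = 3.30e-07, and adjusted p = 0.0735 with an estimated correlation). Of 18 T cell receptor response genes 1 did, Myc (interaction -4.16, adjusted p = 0.0283), with 1 in each direction adjusted over the list alone, a median of -1.15 and an adjusted p of 0.00271 (adjusted p = 0.0998 with an estimated correlation). Of 20 immediate early genes 1 did, Egr1 (interaction -4.79, adjusted p = 0.0188), with 3 adjusted over the list alone, a median of -1.09 and an adjusted p of 5.26e-06 (adjusted p = 0.141 with an estimated correlation). No member of the NF-kB list passed (median -0.49, adjusted p = 0.044, and adjusted p = 0.639 with an estimated correlation). As many as these 5 lists were called in 32 of 100 draws with permuted residuals, so chance cannot be excluded for their number. Markers of other cell types did not pass as lists in the interaction (adjusted p from 0.106 to 0.697). Of the 21 called genes among the 118 followed, 13 kept their calls whichever library was left out, and Klrg1, Il1rl1, Ccr3, Myc and Snapc2 were among the 8 that did not. Only 3 of the 21, Apol9b, Lgmn and S100a6, kept their calls in every setting tried.

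**Figure D4:**
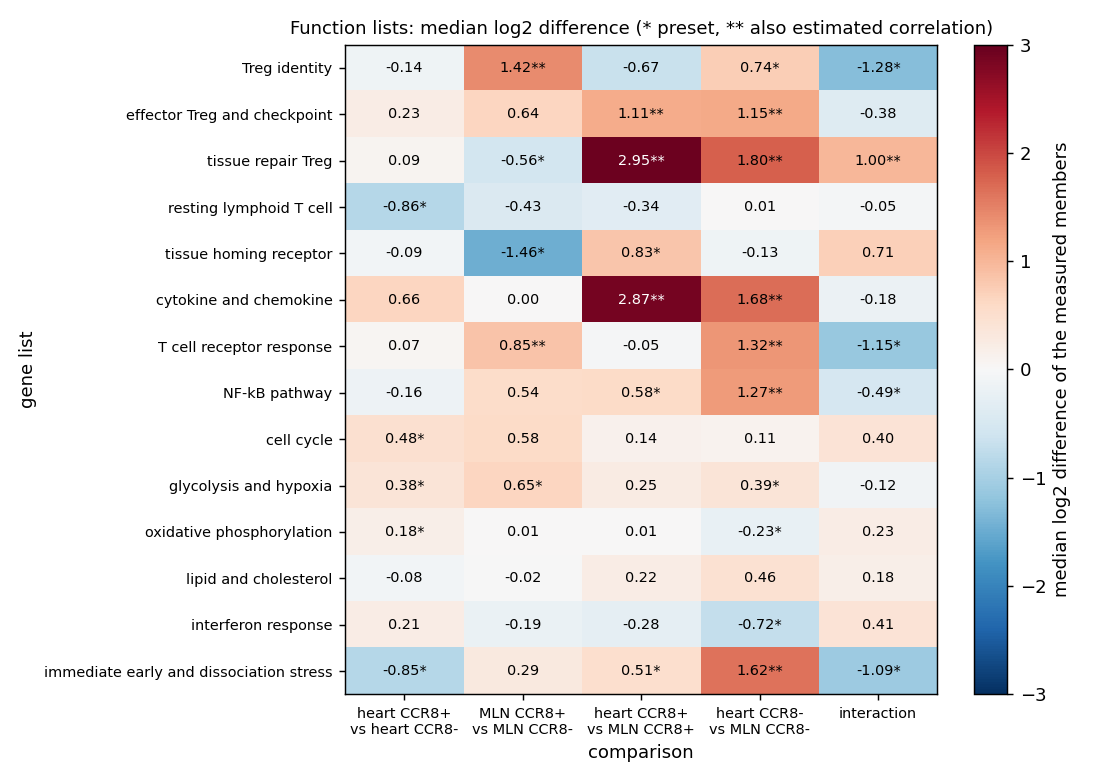
Median log2 difference of the measured genes of the 14 function lists (vertical) in the 5 comparisons (horizontal), with 1 asterisk where the list passed with the preset correlation and 2 where it also passed with an estimated one. Tissue repair genes have medians of 2.95 in heart CCR8+ against MLN CCR8+ and 1.80 in heart CCR8- against MLN CCR8- Tregs.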

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

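The tests of other heart cells, B cells and antigen-presenting cells, swapped labels, captured transcripts, a single library and permuted residuals were chosen only after the results were seen. The intervals given with medians come from resampling genes, which are not independent, and leave out the spread between libraries.

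A library stood apart where its gap to the nearest of the 3 others exceeded Dixon's critical value for groups of 4, as a share of the range of its group. This held for 61 of 472 groups of 1 gene, where chance gives about 1 in 20 groups, or 23.6, and for 6 of 96 groups of a list mean, where chance gives 4.8. The highest numbers were in MLN CCR8- replicate 3 (13) and heart CCR8- replicate 3 (12). Many of the genes were at or near 0 in the other libraries of the group.

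In heart CCR8- Tregs these values stood apart, each given with the range of the 3 other libraries. In replicate 1 they were Il10 9.099 (7.117 to 7.176) and Tff1 1.493 (all others 0). In replicate 2 it was Il1r2 7.371 (6.471 to 6.603). In replicate 3 they were Batf 7.55 (8.634 to 8.857), Cxcr6 2.106 (6.981 to 7.678), Galk1 3.329 (0 to 0.1388), Gpr83 1.009 (2.538 to 2.797), Mlf1 3.082 (all others 0), Pdzk1ip1 0.1817 (all others 0), Sparc 10.8 (6.987 to 7.509), Tnfrsf9 7.141 (7.904 to 8.025), Tnnt2 1.84 (all others 0), the resting lymphoid T cell list mean 6.01 (5.657 to 5.714), the tissue homing receptor list mean 3.548 (4.84 to 4.979) and the glycolysis and hypoxia list mean 4.809 (5.201 to 5.253). In replicate 4 they were Cd79a 1.506 (0 to 0.03949), Haus5 1.042 (2.924 to 3.281), Nudt22 3.525 (all others 0), S1pr1 8.441 (8.222 to 8.232) and Slc22a2 3.043 (0 to 0.2152).

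In heart CCR8+ Tregs these values stood apart, each given with the range of the 3 other libraries. In replicate 1 they were Gna15 5.99 (5.082 to 5.219), Mgp 0.5998 (6.923 to 8.13), Selenoo 1.5 (0.04963 to 0.12), Spp1 0.4195 (5.986 to 6.824) and Tnnt2 0 (2.753 to 3.154). In replicate 2 they were Apobec2 0.7086 (all others 0), Cd83 8.784 (7.778 to 7.822), Fdxr 1.868 (0 to 0.147), Myc 2.865 (5.231 to 5.519), Ramp3 8.493 (8.123 to 8.173) and the glycolysis and hypoxia list mean 5.171 (5.595 to 5.636). In replicate 3 it was Haus5 1.483 (0 to 0.12). In replicate 4 they were Ctla4 10.78 (10.02 to 10.14), Gapdh 10.84 (10.54 to 10.56), Il2ra 6.016 (6.773 to 6.898), Nudt22 4.032 (0 to 0.4655) and the resting lymphoid T cell list mean 5.545 (4.651 to 4.8).

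In MLN CCR8- Tregs these values stood apart, each given with the range of the 3 other libraries. In replicate 1 it was Foxp3 5.721 (4.869 to 4.92). In replicate 2 they were Cd79a 6.507 (2.016 to 2.546) and H2-Ab1 7.451 (0 to 1.159). In replicate 3 they were Atf3 0.1865 (all others 0), Atp5md 10.12 (10.29 to 10.31), C1qb 0.2768 (all others 0), Calca 0.338 (all others 0), Cd14 0.1865 (all others 0), Cxcl2 0.2768 (all others 0), Cxcr5 5.745 (4.144 to 4.282), Fabp4 0.6583 (all others 0), Havcr2 1.735 (all others 0), S100a4 11.49 (12.82 to 13.01), Slc22a2 2.259 (all others 0), Smyd2 2.87 (all others 0) and Tnfrsf1b 3.336 (4.015 to 4.15). In replicate 4 they were Bhlhe40 1.805 (4.75 to 5.207), Csf2 2.312 (all others 0) and Dpt 0.3394 (all others 0).

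In MLN CCR8+ Tregs these values stood apart, each given with the range of the 3 other libraries. In replicate 1 it was the neutrophil list mean 1.019 (0.32 to 0.4302). In replicate 2 they were Atf3 0.05485 (all others 0), Dcn 2.328 (0 to 0.1102) and Rora 2 (1.152 to 1.284). In replicate 3 they were Calca 1.168 (all others 0), Haus5 1.062 (2.993 to 3.274) and Tyrobp 4.979 (all others 0). In replicate 4 they were Ier3 2.139 (0 to 0.05866), Lgmn 0.1336 (all others 0), Ramp3 2.288 (all others 0) and Zbp1 6.806 (7.379 to 7.494).

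The CCR8 difference of 21 of the 118 genes followed differed between heart and MLN by the interaction test in limma. It was more positive in heart for Ccr2 4.835, Ccr3 5.884, Csf2 3.457, Glrx 2.611, Ifi27l2a 1.207, Il1rl1 3.479, Klhl28 5.588, Klrg1 7.75, Lgmn 6.017, Ly6a 1.352, S100a4 6.625, S100a6 4.525, Tff1 5.425 and Tigit 1.981 (log2). It was more negative in heart for Apol9b -4.61, Dpt -3.13, Egr1 -4.789, Haus5 -4.838, Izumo1r -2.352, Myc -4.16 and Snapc2 -4.444.

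Other splits of the libraries tested whether the numbers of called genes exceed chance. In heart CCR8+ against CCR8- Tregs 1 of 35 splits, the real one, gave as many as 38 genes (highest other 9). In MLN CCR8+ against CCR8- 1 of 35 gave 429 (highest other 4). In heart CCR8+ against MLN CCR8+ 1 of 35 gave 1015 (highest other 3). In heart CCR8- against MLN CCR8- 1 of 35 gave 473 (highest other 3). With 35 splits no count can be rarer than 1 of 35, so chance is unlikely for each count but not excluded. The splits of 2 comparisons at once decide nothing, because mixing the libraries removes the differences a shared count needs, and can remove a difference in 1 tissue while keeping the other, which then counts as interaction. As many were reached by 3 of 100 for the interaction genes (real 42, highest other 145), 47 of 100 for its lists (real 5, highest other 9), 1 of 100 for the genes shared by CCR8 (real 10, highest other 0) and 1 of 100 for those shared by tissue (real 239, highest other 0).

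For the interaction, the residuals of a model with no interaction were permuted over the libraries instead, which assumes the same spread in all groups. The 42 genes were reached by 1 of 100 draws, the real one (highest other 2), so chance is unlikely for this count under that assumption. The 5 lists were reached by 32 of 100 draws (highest other 10), so for these chance cannot be excluded.

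For the numbers of called gene lists with the preset correlation, chance cannot be excluded in the 2 comparisons of CCR8+ against CCR8-. In the 2 comparisons of heart against MLN the splits decide nothing. Besides the real split, only splits that keep 3 libraries of a group together called as many, and these keep part of the real difference. Splits that mixed the 2 groups evenly called at most 8 lists in either of these 2 comparisons. As many lists were called in 8 of 35 splits for heart CCR8+ against CCR8- (real 7, highest other 9), 4 of 35 for MLN CCR8+ against CCR8- (6 and 7), 5 of 35 for heart CCR8+ against MLN CCR8+ (9 and 11) and 2 of 35 for heart CCR8- against MLN CCR8- (13 and 14).

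Tissue repair genes were higher in heart CCR8+ than in MLN CCR8+ Tregs, with a median of 4.70 over the 12 called members. With the score of fibroblast, macrophage and endothelial markers as a covariate the median was 3.82 (95% interval over genes 2.75 to 5.52). The 13 called markers of these cells went from a median of 3.705 to 1.453 with the same covariate, so the score removes such RNA only in part. The tissue repair members fell less than these markers, which argues against RNA of other heart cells as the whole cause. The interval leaves out the spread between libraries, and the 12 members were chosen by their calls in this comparison. With the mean of the immediate early list as a covariate the median was 3.73 (3.16 to 5.46). This argues only against stress from tissue dissociation that follows this list within groups. A dissociation effect common to all heart libraries cannot be told apart from tissue. Part of the pattern stays open, since only 8 of the 12 members still passed with the first score. Sparc went from 4.81 to 1.68, while Furin, Nfil3 and Pparg lost their calls (adjusted p = 0.0648, 0.0751 and 0.0572) with larger differences. A difference between CCR8+ Tregs of the organ and of its node may explain the rest, as a hypothesis found and tested on the same data.

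Of the genes that differed between the MLN groups, 217 were lower in CCR8+ Tregs, with a median of -1.66. Dilution by RNA of B cells and antigen-presenting cells is argued against by a median of -0.000844 (-0.301 to 0.705) for 12 general T cell genes. Swapped labels are argued against by Ccr8, whose lowest value in MLN CCR8+ lies 1.98 above the highest in MLN CCR8-. The lowest number of genes above 0 in MLN CCR8+ lies 135 above the highest in MLN CCR8-. This cannot decide whether fewer Treg transcripts were captured in MLN CCR8+. Read depth is unknown, and RNA of other cells also adds to the genes above 0. A different mix of Treg states on the 2 sides of the sort may underlie the pattern and was not tested.

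Immediate early genes were lower as a list in heart CCR8+ than in heart CCR8- Tregs, with a median of -0.848 over 20 genes. That heart CCR8- replicate 3 alone made the call is argued against by an adjusted p of 0.00442 and a median of -0.597 without it. RNA of other heart cells cannot be told apart, since with the marker score as a covariate the median was -0.541 (-0.872 to -0.298), an interval that spans the value at which the score would count as the cause. The call itself was lost with an estimated correlation (adjusted p = 0.276), so the pattern may also be variation shared by these genes.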

How the results depend on the processing

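The covariate for other cell types and the fit without 2 heart libraries (CCR8- replicate 3 and CCR8+ replicate 2) were chosen after seeing the data, and the other alternatives were planned.

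Of 590 tests of single genes, 231 of them called, the alternatives other than leaving out 1 library gave 6362 results: 5977 kept their direction and side of the threshold, 347 lost the call, 38 gained 1 and 0 reversed. Leaving out each library in turn gave 9440 results: 8919 the same, 468 lost, 53 gained and 0 reversed. Rescaling each library to the same sum and quantile normalization test little, since the values already share a distribution.

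With no filter on low values, 13 genes were called in heart CCR8+ against CCR8-, 305 in heart CCR8- against MLN CCR8-, 18 in the interaction, 3 shared by CCR8 and 156 shared by tissue, with more genes tested. With only the 2 groups compared, which leaves fewer libraries, 5 were called in heart CCR8+ against CCR8-, 169 in MLN CCR8+ against CCR8- and 204 in heart CCR8- against MLN CCR8-. With other cell types as a covariate the counts were 17 in heart CCR8+ against CCR8-, 406 in heart CCR8+ against MLN CCR8+, 16 in heart CCR8- against MLN CCR8-, 5 shared by CCR8 and 14 shared by tissue. The median size of the 1015 differences of heart CCR8+ against MLN CCR8+ went from 2.06 to 1.90 and their median standard error from 0.478 to 0.614, and for the 473 of heart CCR8- against MLN CCR8- from 2.20 to 1.78 and from 0.501 to 0.784. Without the 2 heart libraries 11 genes were called in heart CCR8+ against CCR8- and 2 were shared by CCR8. With camera and an estimated correlation the lists called numbered 0 in heart CCR8+ against CCR8-, 2 in MLN CCR8+ against CCR8-, 3 in heart CCR8+ against MLN CCR8+, 6 in heart CCR8- against MLN CCR8- and 1 in the interaction, and fry called 2 in heart CCR8+ against CCR8-.

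The replicate block, which treats equal replicate numbers as pairs, gave 20 genes in heart CCR8+ against CCR8- and 6 shared by CCR8, and the cause was not tested. Deviations from the group means had correlations of -0.0933 to 0.0589 in 24 such pairs, so no pairing was seen across all genes. This does not exclude pairing for single genes, and whether equal numbers share mice is unknown.

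Leaving out 1 library gave 3 to 52 genes in heart CCR8+ against CCR8- (3 without heart CCR8+ replicate 3, 4 without heart CCR8+ replicate 1, 8 without heart CCR8+ replicate 2, 11 without heart CCR8- replicate 2) and 3 to 9 lists (3 without heart CCR8- replicate 3). It gave 273 to 469 genes in MLN CCR8+ against CCR8- (273 without MLN CCR8+ replicate 4, 283 without MLN CCR8+ replicate 1), and 266 to 483 in heart CCR8- against MLN CCR8- (266 without MLN CCR8- replicate 4, 286 without MLN CCR8- replicate 3). Heart CCR8+ against MLN CCR8+ had 696 to 1115. The interaction had 28 to 62 genes and 4 to 8 lists (8 without MLN CCR8- replicate 2). Shared by CCR8 were 1 to 12 genes (1, 2 and 3 without heart CCR8+ replicates 3, 1 and 2, 4 without heart CCR8- replicate 2 or MLN CCR8+ replicate 2, 5 without MLN CCR8+ replicate 1, 6 without MLN CCR8- replicate 1). Shared by tissue were 152 to 251 (152 without MLN CCR8- replicate 4, 154 without MLN CCR8- replicate 3).

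Read depth is unknown, so a gene listed at 0 may be expressed below detection, and the drop from 38 to 13 genes with no filter on low values shows how far the weakest comparison rests on the set of genes tested.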

Other observations

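The test of a heart Treg program in this part was chosen before its result was seen, and the genes given as values were picked after theirs were seen.

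Genes of receptors for CGRP, a product of Calca, were measured in the same Tregs. Ramp1, a subunit of the CGRP receptor, lay between 5.18 and 6.35 in heart CCR8-, 5.22 and 6.81 in heart CCR8+, 4.63 and 5.99 in MLN CCR8- and 5.58 and 6.54 in MLN CCR8+ libraries. Calcrl, the other subunit, lay between 2.33 and 3.47 in heart CCR8-, 1.38 and 2.26 in heart CCR8+, 1.65 and 3.06 in MLN CCR8- and 1.01 and 1.83 in MLN CCR8+ libraries.

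Of the genes called higher with CCR8 in both tissues, Mif, a cytokine, lay between 10.66 and 11.16 in heart CCR8+ and 9.46 and 9.90 in heart CCR8- libraries. Nme1, a nucleoside diphosphate kinase, lay between 8.54 and 9.02 in heart CCR8+ and 7.72 and 8.05 in heart CCR8- libraries. In the MLN, Bmyc lay between 9.33 and 9.80 in CCR8+ and 5.67 and 7.06 in CCR8- libraries. Ribosomal protein genes made up 34.8 ± 1.0% of the summed expression in MLN CCR8+ libraries, against 29.2 ± 1.5% in MLN CCR8-, 28.3 ± 1.4% in heart CCR8+ and 29.0 ± 1.5% in heart CCR8-.

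Within MLN CCR8- Tregs, replicates 1 and 2 lay apart from 3 and 4 on the third principal component (-64.95 and -43.66 against -1.74 and 9.31) and on the fifth (-30.97 and -41.25 against 31.43 and 22.60). A batch as the reason was not tested. Ramp3 was 8.38 and 7.85 in the first pair and 2.51 and 3.83 in the second, and Ctla4 10.03 and 9.90 against 7.66 and 8.04. Ramp1 was 4.63 and 4.68 in the first pair and 5.99 and 5.96 in the second, Mif 9.25 and 9.62 against 10.28 and 10.27, and Psmb8 9.35 and 9.54 against 10.09 and 10.05.

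Some lists passed in none of the 5 comparisons with camera and the preset correlation. The lowest adjusted p by camera was 0.2 for lipid and cholesterol genes, 0.0548 for neutrophil and for general T cell genes, 0.464 for cytotoxic T and NK cell genes and 0.505 for erythroid genes, and B cell genes were not tested as a list because 4 were measured. With fry the neutrophil list passed in heart CCR8+ against CCR8- (adjusted p = 0.0435, median -0.61) and in heart CCR8- against MLN CCR8- (adjusted p = 0.0267, median 0.88). In a few lists that did not pass, the median and the mean had opposite signs, as for T cell receptor response genes in heart CCR8+ against MLN CCR8+ (median -0.05, mean 0.32).

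A heart Treg program already present in MLN CCR8- cells may underlie the 217 genes that were lower in MLN CCR8+ Tregs. If so, these genes would be higher in heart CCR8- than in MLN CCR8- Tregs. Their median difference was -8.7e-05 (95% interval over genes, not libraries, -0.0775 to 0.168), with 29 called higher and 15 called lower in heart CCR8-. The test leaves the hypothesis undecided, because the same MLN CCR8- libraries define the genes and enter the comparison.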
